A study of Homo sapiens with 16 samples.

How the data were processed

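RNA from human BJ foreskin fibroblasts was measured on 16 Affymetrix Human Genome U133 Plus 2.0 arrays, 1 array per sample: 4 samples treated with bleomycin (100 µg/ml for 24 h), 6 replicative senescent samples (population doublings above 85, senescence judged by SA-βgal staining per the labels) and 6 young samples. Serum was withheld for 72 h before RNA was taken with TRIzol, per the series design text. That text speaks of mock-treated as well as bleomycin-treated cells, while the sample labels name no mock group beside young. The labels give 3% oxygen for the replicative senescent and young samples and no oxygen level for the bleomycin samples. Whether the arrays of a group came from separate cultures, and when they were processed, is not given in the sources used here.

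The deposited values were intensity values on a linear scale, as their range showed (lowest 0.87, median 20.5, highest 11277). Quality control, analysis and clustering were done by the authors in dChip (release of May 2008), per the series design text. The expression model, background step and normalization behind the deposited values are not given in the sources used here. The rule of the study for a change, per the same text, was a lower 90% confidence bound of the fold of at least 1.5 together with an intensity difference of at least 75. It served as an alternative.

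Values were used as deposited, since the medians of the 16 arrays spanned 0.20 on the log2 scale, under the limit of 0.5 set beforehand for quantile normalization. Intensities below 10.1, the 30th percentile of all values, were set to that floor and all values were put on the log2 scale. A probe set was kept if it lay above the floor on at least 4 of the 16 arrays. Of 54675 probe sets, 41097 carried 1 gene symbol, 1801 several and 11777 none. Of those with 1 symbol 33972 passed the filter, and the brightest probe set stood for each of 17270 genes. With several probe sets per gene kept for 8702 genes, the choice of probe set could matter and was varied. Some genes were not analysed here.

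Changes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, all 16 arrays in a joint fit with group as the only factor, 13 residual degrees of freedom and a prior of 3.44). P-values were adjusted by the Benjamini-Hochberg method over all genes, and a gene was called at an adjusted p under 0.05. Gene lists were written before the values were seen (27 lists, 813 different genes, 731 of them tested). The lists were tested with camera in limma with a preset correlation between genes of 0.01, adjusted over lists, and again with the correlation estimated from the data. Members of each list were also adjusted over the list alone. The named genes were fixed by rule beforehand. They were, in each comparison, the 8 highest and 8 lowest called genes whose groups did not overlap on any array, 16 genes chosen from the literature on senescence (SPP1 and cell cycle, cytokine, protease and IGF-binding genes), up to 4 called members of each described list, and any called member against the direction of its list. Genes set out for both senescent effects together were chosen after their values were seen. Array quality was compared by exact permutation tests of the array median, the share of probe sets above the floor and the 3′ to 5′ ratios of ACTB and GAPDH.

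Arrays carry replicate numbers. Deviations from the group means of replicative senescent and young arrays of the same number correlated at 0.146 to 0.510 across genes, all above the bound of 0.1 set beforehand. The numbers thus passed that rule, as a finding from the data and not from the labels. Only 2 of 6 replicative senescent arrays, however, correlated best with the young array of their own number. Array 3 correlated more with young array 4 (0.219) than with young array 3 (0.146), so the rule does not single out the number. With the number as a replicate block 6256 genes changed between replicative senescent and young arrays, against 5877 without it, and the same 10 lists were called. Unblocked values are given although the numbers passed the rule, and named genes whose calls ended under the block are identified in the text.

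The gene step was tested on simulated data with 200 changed genes, all with young means above the floor. Noise was drawn independently for each array and gene, with the spread of that gene on the real arrays. The gene step called 41.8% (bleomycin against young) and 44.8% (replicative senescent against young) of genes changed 1.5-fold, 97.0% and 89.6% of those changed 2-fold, and 98.5% of those changed 4-fold in either case. False calls made up 6.51% and 5.49% of all calls. These shares hold only for independent noise. With no change simulated, the median count of calls over 20 runs was 0 with noise independent between arrays. With noise shared by neighbouring arrays, and by all 4 bleomycin arrays, it was 1003 (bleomycin against young) and 160 (replicative senescent against young). For bleomycin against replicative senescent it was 1009.5. Bleomycin neighbours were no more alike than other bleomycin arrays, so 1003 and 1009.5 rest on counting that group as 1 sample. Once the arrays that shared noise were averaged, the median count was 0 for replicative senescent against young. For that reason a fit on averaged neighbouring arrays, with the bleomycin arrays as 1 sample (4 residual degrees of freedom), was added after seeing the data.

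Alternatives chosen beforehand were quantile normalization, median centring, other floors and filters, the mean of probe sets, probe sets open to shared sequence left out, every probe set tested alone, trended and robust eBayes, array weights, the compared groups alone, the replicate block, a fold of 1.5, treat, the rule of the study, fry in place of camera, and each array left out in turn. Added after seeing the data were averaged neighbouring arrays (3 forms), neighbouring arrays as a random effect, arrays 1 and 2 left out, and a floor at an intensity of 75. The random effect took all 4 bleomycin arrays as 1 block. Not every gene whose call ended in a setting chosen beforehand is marked where it is named. The full list is given with the dependence on processing. To judge genes shared by both senescent effects, unchanged groups were simulated 100 times against the real young arrays, and the young arrays were split 3 and 3 in all 20 ways.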

Results

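Gene expression was measured with Affymetrix U133 Plus 2.0 arrays in BJ cells, a strain of human foreskin fibroblasts kept in culture. The 16 arrays fell into 3 groups. In the bleomycin group (4 arrays) the cells had received 100 µg/ml of bleomycin, an antibiotic that breaks DNA, for 24 h to bring on stress-induced premature senescence. The replicative senescent group (6 arrays) held cells passaged beyond 85 population doublings, and the young group (6 arrays) held cells labelled young. Cells of all groups were starved of serum for 72 h before RNA was taken.

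Median intensity per array ranged from 18.8 to 21.6, and between 67.0% and 72.2% of probe sets lay above the floor of 10.1. The ratio of 3′ to 5′ signal for ACTB, a measure of RNA integrity, was 2.14 ± 0.773 (SD, n = 6) in replicative senescent, 1.57 ± 0.299 (n = 6) in young and 1.64 ± 0.110 (n = 4) in bleomycin arrays. None of 12 exact permutation tests of array quality passed after adjustment (lowest adjusted p = 0.229), and 2 of them had an unadjusted p under 0.05. These tests took no account of the replicate numbers. Arrays with neighbouring numbers (1 and 2, 3 and 4, 5 and 6) were more alike than other arrays of their group among replicative senescent and young arrays. The SD of their log2 difference was 0.25 to 0.34 among replicative senescent arrays against 0.37 to 0.54 for the other array pairs, and 0.28 to 0.37 against 0.43 to 0.56 among young arrays. Among bleomycin arrays it was 0.32 to 0.38 against 0.33 to 0.39. Nothing in the labels says that arrays of a group came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

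**Figure D1:**
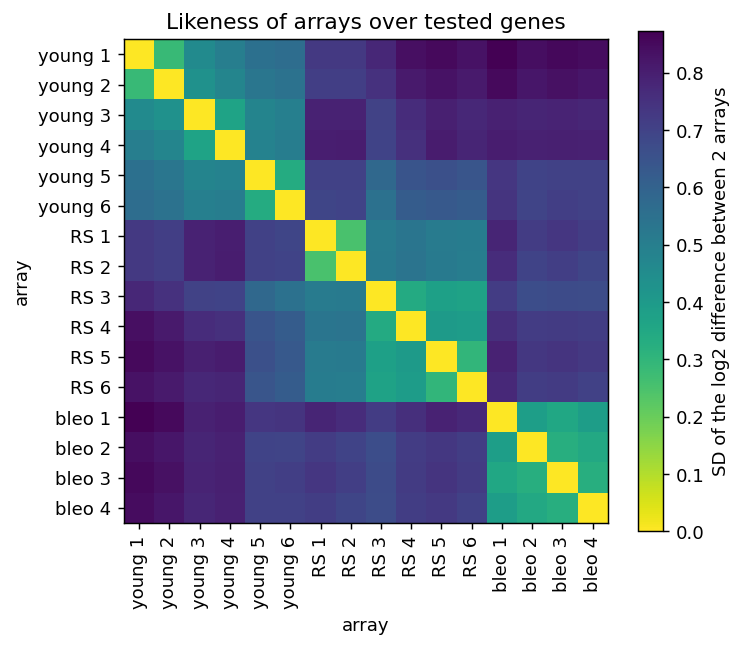
SD of the log2 difference between each pair of arrays over the tested genes, with arrays in the order young, replicative senescent (RS) and bleomycin (bleo) on both axes. Neighbouring arrays of the young group differed by 0.28 to 0.37 and its other array pairs by 0.43 to 0.56.

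The comparison of bleomycin-treated with young cells asked what stress-induced senescence changed in the transcriptome, with osteopontin as the factor named in the title of the series. SPP1, which encodes osteopontin, a secreted phosphoprotein, rose 32.9-fold, from an intensity of 13.6 ± 6.53 (SD, n = 6) in young to 453 ± 73.1 (n = 4) in bleomycin arrays (log2 5.04 ± 0.31 SE, adjusted p = 2.8e-09). The neutrophil-attracting chemokines CXCL5 (142-fold, log2 7.15 ± 0.16 SE, adjusted p = 1.8e-14) and CXCL8 (117-fold, log2 6.87 ± 0.28 SE, adjusted p = 3.2e-11) and the matrix-degrading enzyme MMP3 (122-fold, log2 6.94 ± 0.28 SE, adjusted p = 2.9e-11) had the largest increases. The inflammatory cytokines IL6 (155 ± 55.2 to 4046 ± 1218) and IL1B (37.7 ± 6.20 to 1292 ± 975) rose 26.9-fold and 29.2-fold.

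Other genes among the 8 largest increases, taken over genes whose groups did not overlap on any array, were the decoy receptor IL13RA2 (57.9-fold), the chemokines CXCL2 (44.0-fold) and CXCL1 (43.9-fold), KCTD4 (at least 40.5-fold, since every young array was at the floor) and EREG, a ligand of the EGF receptor (36.8-fold). The calls of CXCL2 and of DNM1, named next, did not hold in every setting chosen beforehand. The largest decreases were those of IL17RD (24.4-fold lower, log2 −4.61 ± 0.25 SE, adjusted p = 7.4e-10), the prostacyclin synthase PTGIS (19.4-fold), the collagen gene COL21A1 (18.3-fold), the dynamin DNM1 (17.8-fold), OLFML1 (17.2-fold), RARRES2 (16.5-fold), EGFL6 (15.4-fold) and the microfibril-associated MFAP4 (15.1-fold). SPP1 was above the floor on 5 of 6 young arrays, IL13RA2 on 4, CXCL5 on 3 and H2BC4, COL10A1 and AKR1B10 on 2, and COL21A1 and EGFL6 on 2 of 4 bleomycin arrays, so these folds depend on the floor. For SPP1 the log2 difference ranged from 4.43 to 5.27 over the settings chosen beforehand, and its other probe set had mean intensities below the floor in all 3 groups (4.72 in young, 4.44 in replicative senescent and 7.23 in bleomycin arrays). Among genes named beforehand, the cell cycle inhibitor CDKN1A (p21) rose 2.80-fold (adjusted p = 3.1e-07), while CDKN2A, which encodes p16 and ARF, was 3.03-fold lower (adjusted p = 2.0e-08). The nuclear lamina gene LMNB1 was 2.14-fold lower and the proliferation marker MKI67 1.49-fold lower. CDKN2B differed by −0.06 on the log2 scale and did not pass (adjusted p = 0.801). MMP1, a collagenase, rose 5.53-fold, IGFBP5 rose 1.90-fold and IGFBP3 was 7.46-fold lower. The brightest probe set of IL1A did not pass (log2 −0.42 ± 0.29 SE, adjusted p = 0.277), but with the floor and filter at the 50th percentile, where its other probe set was tested, the gene rose by 2.01 on the log2 scale (adjusted p = 4.6e-08; over the settings chosen beforehand its log2 difference ranged from −0.42 to 2.01 and its adjusted p reached 0.447).

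**Figure D2:**
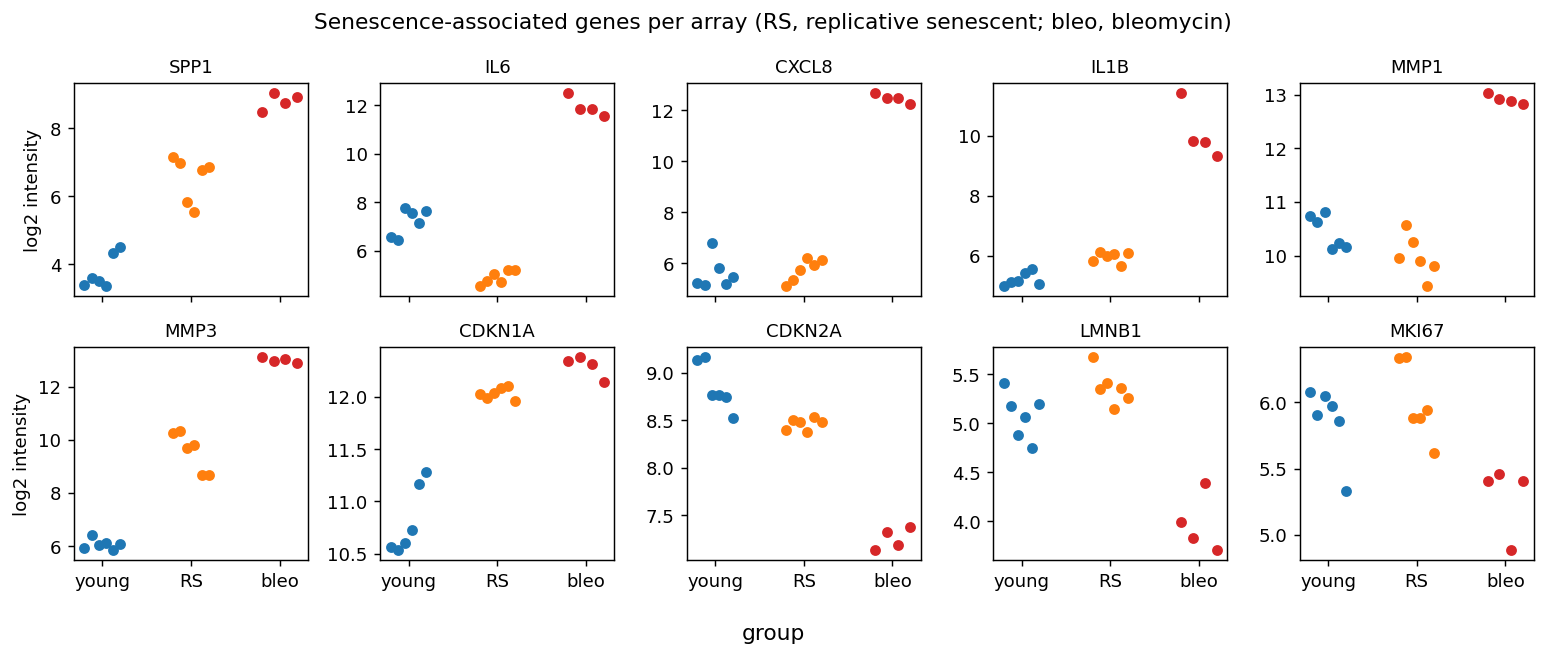
Log2 intensity of 10 senescence-associated genes on each array, 1 point per array, for young, replicative senescent (RS) and bleomycin (bleo) cells; the vertical axes differ between panels. SPP1 lay between 8.50 and 9.05 on the bleomycin arrays and between 3.34 and 4.52 on the young arrays.

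Of 27 measured cytokines and chemokines of the senescence-associated secretory phenotype (SASP), 20 rose and 2 fell (21 and 2 adjusted over the list alone), and the list shifted up (camera adjusted p = 5.6e-13, and adjusted p = 0.0182 with an estimated correlation). CXCL12, a chemokine that fibroblasts make in quantity (13.9-fold lower), and IL15 (1.67-fold lower) went against it. Among 25 matrix proteases and inhibitors 11 rose and 5 fell (12 and 5 adjusted over the list alone), led by MMP3, the protease inhibitor TFPI2 (15.5-fold), MMP1 and SERPINB7 (3.84-fold). The shift of that list had adjusted p = 3.4e-04, and adjusted p = 0.0717 with an estimated correlation. MMP11, ADAMTS9, MMP16, MMP2 and TIMP4 fell. MMP11 changed sign without probe sets open to shared sequence, and the calls of ADAMTS9, MMP16 and MMP2 did not hold in every setting chosen beforehand. For 39 secreted growth factors and IGF-binding proteins the counts were 18 higher and 10 lower (19 and 10 adjusted over the list alone), with EREG, the calcium-regulating hormone STC1 (11.3-fold), the stress cytokine GDF15 (11.2-fold) and HBEGF (10.2-fold) on top. The upward call was marginal (adjusted p = 0.0486, and adjusted p = 0.243 with an estimated correlation), and IGFBP3, WNT2, IGFBP2, BMP4, IGFBP6, TGFB1, VEGFA, KITLG, DKK1 and TGFB3 fell. Regulators of NF-kB, the transcription factor behind many inflammatory genes, also shifted up, and of 19 members 9 rose and 3 fell (9 and 3 adjusted over the list alone; adjusted p = 0.00420, and adjusted p = 0.228 with an estimated correlation). PTGS2 (COX-2) rose 7.26-fold, IRAK2 5.95-fold, NFKBIZ 4.90-fold and TNFAIP6 2.37-fold, whereas RELA, IRF1 and BIRC2 fell by less than 1.5-fold.

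Among 33 targets of the tumour suppressor p53, 17 rose and 4 fell (18 and 5 adjusted over the list alone), including GDF15, TIGAR (6.34-fold), GADD45A (4.97-fold) and CYFIP2 (4.62-fold). The list shifted up (adjusted p = 4.5e-05, and adjusted p = 0.252 with an estimated correlation), and ACTA2, CCNG1, DDB2 and XPC fell. The 13 cell cycle inhibitors and pocket proteins shifted down as a list (adjusted p = 0.0352, and adjusted p = 0.228 with an estimated correlation). In it 8 genes fell, such as CDKN1C (3.52-fold) and CDKN2A, and the 2 that rose, CDKN1A and GADD45A, are also p53 targets (2 and 8 adjusted over the list alone). Genes of mitosis and G2 did not shift as a list (median log2 −0.14, adjusted p = 0.137, and adjusted p = 0.814 with an estimated correlation). Of the 58, 3 rose and 16 fell (3 and 10 adjusted over the list alone). CDC25B (2.94-fold) and the spindle motor KIF11 (2.23-fold) fell, and AURKA (4.78-fold), CKS2 (2.40-fold) and PTTG1 (1.55-fold) rose. AURKA did not keep its call in every setting chosen beforehand. Histone transcripts of the polyadenylated and variant type were higher, as 10 rose and 1 fell among 13 (11 and 1 adjusted over the list alone; adjusted p = 2.1e-08, and adjusted p = 0.0717 with an estimated correlation). H1-2 rose 16.2-fold, H2BC4 11.6-fold, H2BC21 9.44-fold and H4C8 5.46-fold, and H1-10 fell 2.76-fold.

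Of 61 genes for fibrillar collagens, elastic fibre and other matrix, 7 rose and 35 fell (7 and 37 adjusted over the list alone), and the list shifted down (adjusted p = 1.5e-07, and adjusted p = 0.0529 with an estimated correlation). MFAP4, the adhesion protein POSTN (13.5-fold) and COL15A1 (13.1-fold) were among the lower genes, while COL10A1 rose 27.5-fold and PLOD2, TNC, NID2, COL7A1, LOX and LOXL3 rose by 1.23-fold to 2.13-fold. Genes that mark fibroblast identity shifted down with 0 members higher and 11 of 22 lower (0 and 13 adjusted over the list alone; adjusted p = 1.0e-04, and adjusted p = 0.0137 with an estimated correlation). These included DPT (4.76-fold) and TWIST1 (3.73-fold), TBX5 (3.23-fold) and the growth factor receptor PDGFRA (2.71-fold). Of 11 leukocyte markers 3 rose, SRGN (5.49-fold), PTPRC (at least 2.58-fold, to an intensity of 26.5 ± 5.08) and LAPTM5 (1.31-fold), and none fell (2 and 0 adjusted over the list alone; adjusted p = 0.0497, and adjusted p = 0.162 with an estimated correlation).

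Among 32 genes of the unfolded protein response and ATF4, 22 rose and 4 fell (23 and 4 adjusted over the list alone; adjusted p = 9.8e-07, and adjusted p = 0.228 with an estimated correlation). The transcription factor ATF3 rose by 3.91 on the log2 scale, CHAC1 8.31-fold and the cystine transporter SLC7A11 3.64-fold, and PHGDH, SHMT2, CALR and ATF4 itself fell. CALR changed sign without probe sets open to shared sequence, and the call of SHMT2 did not hold in every setting chosen beforehand. Antioxidant genes under NRF2 shifted up (adjusted p = 3.4e-05, and adjusted p = 0.228 with an estimated correlation), as 20 rose and 4 fell of 35 (20 and 4 adjusted over the list alone). TXNRD1 rose 3.28-fold and AKR1B10 3.32-fold, whereas SOD3 (4.89-fold lower), GPX4, CAT and TKT fell, though TKT changed sign without probe sets open to shared sequence. Interferon-stimulated genes, which respond to antiviral signalling, shifted up (adjusted p = 1.5e-07, and adjusted p = 0.405 with an estimated correlation), and of 43 25 rose and 2 fell (29 and 2 adjusted over the list alone), with ISG15 (4.80-fold), MX1 (4.71-fold), OAS2 (4.34-fold) and OAS1 (4.20-fold) on top and PSMB9 and PSMB8 lower. In cholesterol synthesis 9 rose and 1 fell of 19 (10 and 2 adjusted over the list alone; adjusted p = 0.0144, and adjusted p = 0.405 with an estimated correlation). EBP (2.49-fold), SC5D (2.32-fold), MSMO1 (2.26-fold) and IDI1 (2.14-fold) rose and MVK fell. Without probe sets open to shared sequence SC5D and IDI1 changed sign and the list call ended (camera adjusted p = 0.111). The call of MVK did not hold in every setting chosen beforehand.

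Over all 17270 genes tested, 6486 passed, 2948 of them higher and 3538 lower, and 4149 of these changed by at least 1.5-fold. With quantile normalization the balance turned, to 3696 higher and 2947 lower. All bleomycin arrays lay outside the range of the young arrays for 5426 genes (31.4%, where chance gives 0.952% with all arrays as independent samples). The likeness of neighbouring young arrays would raise that chance share. With neighbouring arrays averaged, an alternative chosen after seeing the data, 3566 genes passed with the bleomycin arrays as 2 samples. With these arrays as 1 sample, so that the spread came from the other groups only, 1077 genes passed (446 higher, 631 lower), among them 15 of the 16 genes with the largest changes (DNM1 had adjusted p = 0.0540, and up to 0.916 over the settings chosen beforehand) and 2 fewer of the 14 lists (growth factors, adjusted p = 0.0626, and leukocyte markers, 0.0604). Of 129 called genes picked by the naming rule, 57 did not pass there. List members called higher and lower there numbered 17 and 1 for SASP, 8 and 0 for proteases, 5 and 3 for growth factors, 6 and 0 for NF-kB regulators, 8 and 0 for p53 targets, 2 and 4 for cell cycle inhibitors, 1 and 0 for mitosis and G2, 9 and 0 for histones, 1 and 14 for matrix, 0 and 4 for fibroblast identity, 2 and 0 for leukocyte markers, 5 and 0 for the unfolded protein response, 7 and 1 for NRF2, 2 and 0 for interferon-stimulated genes and 3 and 0 for cholesterol synthesis. With an estimated correlation 2 of the 14 lists passed (SASP and fibroblast identity). Apart from that alternative, the adjusted p of 9 of the 14 lists stayed at or below 0.00873. It reached 0.149 for growth factors (above 0.05 in 9 of 18), 0.156 for cell cycle inhibitors (6 of 18), 0.135 for leukocyte markers (12 of 17), 0.111 for cholesterol synthesis and 0.141 for NF-kB regulators (1 of 18 each, without probe sets open to shared sequence). Leaving out 1 array ended the call of growth factors for 7 of the 16 arrays (highest adjusted p 0.0718, bleomycin array 1), that of leukocyte markers for 10 (0.0826, bleomycin array 1) and that of cell cycle inhibitors for young arrays 5 (0.0629) and 6 (0.0664). Mitosis and G2 shifted down without young array 3 (0.0453) or 4 (0.0151). Among genes picked by the naming rule it ended these calls, given with the array and the highest adjusted p: TGFB1 (bleomycin array 3, 0.0870), TNC (bleomycin array 1, 0.137), LOXL3 (bleomycin array 1, 0.0905), MVK (bleomycin array 4, 0.124), PSMB8 (bleomycin array 1, 0.113), RELA (bleomycin array 3, 0.105), LAPTM5 (bleomycin array 2, 0.137), MMP2 (bleomycin array 3, 0.0644), XPC (bleomycin array 3, 0.0804), PTTG1 (bleomycin array 2, 0.0528) and MKI67 (bleomycin array 3, 0.0698).

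**Figure D3:**
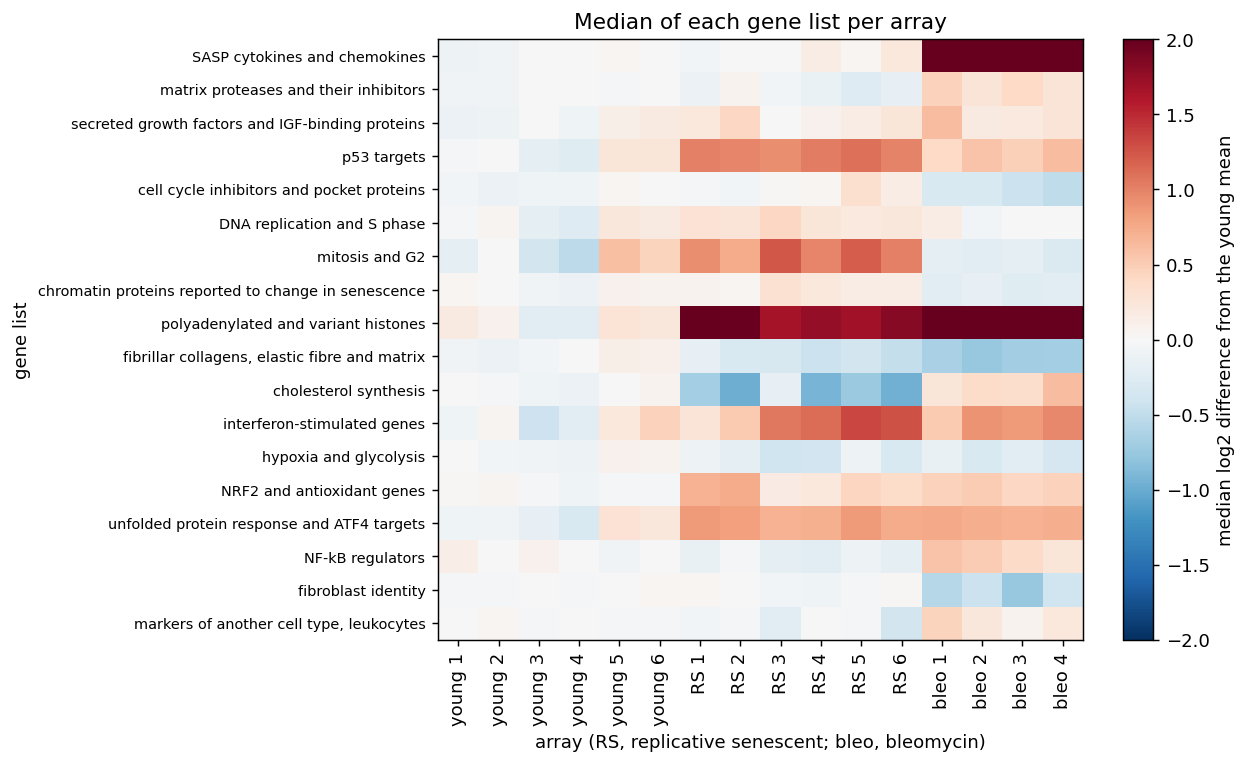
Median log2 difference from the young mean for each described gene list (vertical axis) on each array (horizontal axis; RS, replicative senescent; bleo, bleomycin); the colour scale ends at −2 and 2. The SASP median lay between 2.58 and 4.41 on the bleomycin arrays and between −0.05 and 0.21 on the replicative senescent arrays.

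The comparison of replicative senescent with young cells asked the same of senescence reached by long passage. SPP1 rose 6.72-fold, from 13.6 ± 6.53 (SD, n = 6) to 99.2 ± 38.6 (n = 6; log2 2.75 ± 0.28 SE, adjusted p = 8.9e-07), and MMP3 rose 11.3-fold (log2 3.50 ± 0.25 SE, adjusted p = 1.8e-08). IL6 moved the other way and was 4.83-fold lower (155 ± 55.2 to 30.7 ± 5.88, log2 −2.27 ± 0.23 SE, adjusted p = 9.0e-07), and CXCL8 did not pass (log2 0.14, adjusted p = 0.738). Genes of mitosis and G2 were higher in replicative senescent than in young cells, 49 of 58 of them, though the shift of the list did not pass with an estimated correlation (adjusted p = 0.355). The largest increases were those of SYT1, a calcium sensor of vesicle release (37.2-fold, log2 5.22 ± 0.29 SE, adjusted p = 8.2e-10), the gap junction gene GJA5 (22.7-fold) and the cyclin CCND2 (20.3-fold).

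EREG (20.1-fold), RUNDC3B (20.1-fold), the neurofilament-type gene INA (19.0-fold), WFDC21P (15.9-fold) and SH3GL2 (14.7-fold) completed the 8 largest increases. The BMP antagonist CHRDL1 (45.8-fold lower, log2 −5.52 ± 0.28 SE, adjusted p = 3.1e-10), CNTN3 (44.9-fold), OLFML1 (38.8-fold), the fibrillin FBN2 (29.9-fold), EPB41L3 (27.5-fold), OLFML2A (25.7-fold), the imprinted gene NDN (22.4-fold) and the transcription factor EBF1 (20.3-fold) had the largest decreases. CHRDL1 and CNTN3 were above the floor on 1 of 6 replicative senescent arrays, EPB41L3 on 2, COL14A1 on 3, OLFML1 on 4 and CA12 and CXCL6 on 5. GJA5, INA, SH3GL2 and H2BC4 were above it on 2 of 6 young arrays, RUNDC3B, WFDC21P and TNFRSF10C on 3 and SPP1 on 5. The folds of these genes depend on the floor. CDKN1A rose 2.33-fold (adjusted p = 8.7e-07) and IGFBP5 2.08-fold, and CDKN2A was 1.31-fold lower (adjusted p = 0.00821). MMP1 was 1.38-fold lower and IL1B 1.66-fold higher. LMNB1 (log2 0.29), MKI67 (0.14), CDKN2B (0.12), IL1A (−0.43) and IGFBP3 (0.09) did not pass, with adjusted p from 0.111 to 0.632.

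In the mitosis and G2 list 49 rose and 1 fell (50 and 1 adjusted over the list alone), the median member was 1.0 higher on the log2 scale, and the camera test gave adjusted p = 8.9e-14, and adjusted p = 0.355 with an estimated correlation. HMMR (3.55-fold), the kinase NEK2 (3.34-fold), KIF23 (3.30-fold) and the checkpoint kinase BUB1 (3.26-fold) rose most and CDC25B fell (2.45-fold). KIF23 did not keep its call in every setting chosen beforehand. The ACTB 3′ to 5′ ratio was higher in this group by 0.38 on the log2 scale, a difference that did not pass (exact permutation test, adjusted p = 0.355). That test took no account of the replicate numbers, so it does not show that RNA integrity was alike. On arrays 3 to 6 the ratio was 2.15 to 3.12 in replicative senescent and 1.59 to 1.96 in young cells. On arrays 1 and 2 it was 1.22 to 1.23 over both groups. Of 47 DNA replication and S phase genes 17 rose and 1 fell (19 and 1 adjusted over the list alone; adjusted p = 0.00213, and adjusted p = 0.544 with an estimated correlation), with RRM2 (3.57-fold), TYMS (3.09-fold), the cyclin CCNE1 (2.69-fold) and CDC6 (2.48-fold) higher and PRIM2 lower. Among p53 targets 25 rose and 1 fell of 33 (25 and 1 adjusted over the list alone; adjusted p = 1.6e-12, and adjusted p = 0.117 with an estimated correlation). CYFIP2 rose 8.28-fold, the receptor TNFRSF10C 6.61-fold, TIGAR 5.84-fold and GADD45A 4.51-fold, and ACTA2 fell. Cell cycle inhibitors did not shift as a list (median log2 0.12, adjusted p = 0.730, and adjusted p = 0.839 with an estimated correlation). Of 13, 5 rose and 5 fell (5 and 6 adjusted over the list alone), with GADD45A, CDKN1A and GADD45B (2.15-fold) higher and CDKN1C (2.68-fold), CDKN1B, RBL2, CDKN2A and BTG1 lower. Without probe sets open to shared sequence the GADD45B value was −0.13 on the log2 scale (adjusted p = 0.636, the highest over the settings chosen beforehand). Histone transcripts rose here too, in 11 of 13 cases with none lower (11 and 0 adjusted over the list alone; adjusted p = 3.2e-09, and adjusted p = 0.117 with an estimated correlation), led by H2BC4 (by 3.33 on the log2 scale), H1-2 (8.82-fold), H4C8 (6.86-fold) and H2BC9 (4.03-fold).

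The SASP list did not shift (median log2 0.07, adjusted p = 0.885, and adjusted p = 0.978 with an estimated correlation). Of 27 genes 6 rose and 3 fell (5 and 3 adjusted over the list alone), and IL6, CXCL12 (4.79-fold) and CXCL6 (4.07-fold) were the ones that fell. Matrix genes shifted down (adjusted p = 1.4e-05, and adjusted p = 0.117 with an estimated correlation), as 9 rose and 32 fell of 61 (11 and 33 adjusted over the list alone). FBN2, POSTN (15.9-fold), COL14A1 (9.73-fold) and FMOD (6.29-fold) were the lowest. COL8A1 (2.25-fold), THBS1, LOX, COL10A1, COL15A1, NID2, COL12A1, FBLN1 and LUM rose. Fibroblast identity genes did not shift as a list (adjusted p = 0.434, and adjusted p = 0.465 with an estimated correlation). In it 4 rose and 8 fell of 22 (4 and 8 adjusted over the list alone), with PDGFRA (3.12-fold), PRRX1 (1.98-fold) and DPT (1.72-fold) lower and HOXC10 (1.79-fold), FBLN1, DDR2 and LUM higher.

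The unfolded protein response and ATF4 list shifted up with 26 of 32 members higher and none lower (26 and 0 adjusted over the list alone; adjusted p = 7.3e-12, and adjusted p = 0.117 with an estimated correlation), among them SLC7A11 (8.51-fold), the serine synthesis enzyme PSAT1 (7.95-fold), the asparagine synthetase ASNS (5.21-fold) and CHAC1 (4.89-fold). For NRF2 and antioxidant genes 20 rose and 6 fell of 35 (21 and 8 adjusted over the list alone; adjusted p = 5.8e-04, and adjusted p = 0.456 with an estimated correlation). GCLM, a subunit of the enzyme for glutathione synthesis, rose 4.20-fold and TXNRD1 4.13-fold. AKR1C2 (4.39-fold), AKR1C1, AKR1C3, SOD3, MT1X and ABCC3 fell, though AKR1C1 and ABCC3 stood at 0.35 and 0.08 (log2) without probe sets open to shared sequence. Interferon-stimulated genes shifted up (adjusted p = 1.7e-07, and adjusted p = 0.465 with an estimated correlation), and 31 rose and 4 fell of 43 (33 and 4 adjusted over the list alone). OAS2 rose 7.64-fold, HERC5 5.80-fold, ISG15 4.35-fold and MX1 4.35-fold, and IFI27, PSMB8, PSMB9 and UBE2L6 fell. The list median against the young mean was 0.26 and 0.53 (log2) on replicative senescent arrays 1 and 2, against 1.06 to 1.34 on arrays 3 to 6 and up to 0.47 on young arrays, so the groups overlapped. Cholesterol synthesis shifted down, as 15 of 19 genes fell and none rose (0 and 15 adjusted over the list alone; adjusted p = 9.6e-07, and adjusted p = 0.148 with an estimated correlation). INSIG1 (2.80-fold lower), FDPS (2.29-fold), STARD4 (2.25-fold) and ACAT2 (2.12-fold) led that list. Its median against the young mean was −0.17 (log2) on replicative senescent array 3, where ACAT2 was also higher, and −0.97 to −0.67 on the other 5 arrays. Hypoxia and glycolysis genes shifted down too (adjusted p = 5.8e-04, and adjusted p = 0.355 with an estimated correlation), with 17 of 39 lower and 5 higher (5 and 17 adjusted over the list alone). The carbonic anhydrase CA12 (15.1-fold), ENO2 (6.46-fold), ZNF395 (4.20-fold) and AK4 (3.67-fold) fell, and the glucose transporter SLC2A1 (2.60-fold), VLDLR, HK2, PGAM1 and PFKFB4 rose. ZNF395 and PFKFB4 did not keep their calls in every setting chosen beforehand. The labels state 3% oxygen for these cells and for the young cells alike.

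In all, 5877 genes passed, 3243 higher and 2634 lower, and 3230 of them changed by at least 1.5-fold. The groups did not overlap for 3306 genes (19.1%, where chance gives 0.216% with all arrays as independent samples). That chance share would be higher with neighbouring arrays as repeats. With neighbouring arrays averaged, chosen after seeing the data, 2188 genes passed (1265 higher, 923 lower), and all 16 genes with the largest changes were among them. Of 120 called genes picked by the naming rule, 31 did not pass there. List members called higher and lower there numbered 20 and 0 for p53 targets, 22 and 1 for mitosis and G2, 8 and 0 for S phase, 11 and 0 for histones, 1 and 15 for matrix, 15 and 0 for the unfolded protein response, 10 and 2 for NRF2, 13 and 0 for interferon-stimulated genes, 0 and 8 for cholesterol synthesis and 1 and 12 for hypoxia. With the replicate number as a block the calls of IL1B, CDKN1B, COL10A1 and ABCC3 ended. All 10 list calls ended with an estimated correlation (adjusted p from 0.117 to 0.544). They held under the other alternatives (highest adjusted p = 0.0124, for S phase at an intensity floor of 75) and without any 1 array. Among genes picked by the naming rule, leaving out 1 array ended the calls of MMP1 (replicative senescent array 5, 0.110), COL10A1 (young array 3, 0.0945), ABCC3 (young array 3, 0.109), DDR2 (replicative senescent array 5, 0.107), CDKN1B (replicative senescent array 1, 0.0928), PSMB9 (replicative senescent array 2, 0.0707), IL1B (young array 1, 0.0653), SOD3 (young array 2, 0.0771) and COL12A1 (young array 2, 0.0577), given with the array and the highest adjusted p.

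The direct comparison of bleomycin-treated with replicative senescent cells asked where both kinds of senescence differ. IL6 was far higher after bleomycin (4046 ± 1218, SD, n = 4) than in replicative senescent cells (30.7 ± 5.88, n = 6; log2 7.02 ± 0.26 SE, adjusted p = 7.9e-12), and CXCL8 was 106-fold higher (log2 6.73 ± 0.28 SE, adjusted p = 3.9e-11). CXCL5, at the floor on every replicative senescent array, was at least 159-fold higher. CXCL6 was 121-fold higher, a value that depends on the floor of 3.34 (log2), since the replicative senescent arrays lay between 3.34 and 3.88. SPP1 was 4.90-fold higher (log2 2.29 ± 0.31 SE, adjusted p = 2.7e-05), and with neighbouring arrays averaged the same difference passed with the bleomycin arrays as 2 samples and did not pass with these arrays as 1 sample (adjusted p = 0.0949), where the settings chosen beforehand gave at most 0.000263. SYT1 was 37.0-fold lower after bleomycin (log2 −5.21 ± 0.32 SE, adjusted p = 3.0e-09).

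ASB5 (58.6-fold), TM4SF1 (53.2-fold), the proteoglycan SRGN (49.4-fold) and CHI3L1, a secreted glycoprotein (at least 41.8-fold), were also among the 8 genes most raised after bleomycin relative to replicative senescence. The basement membrane collagen COL15A1 (19.0-fold lower), VIT (17.9-fold), TMTC1 (16.9-fold), the phosphodiesterase PDE8B (15.1-fold), RUNDC3B (14.6-fold), PCDH10 (14.4-fold) and RNF150 (14.4-fold) joined SYT1 among the lowest. IL1B (17.6-fold), MMP3 (10.8-fold) and MMP1 (7.63-fold) were higher after bleomycin. IGFBP3 (7.94-fold), LMNB1 (2.61-fold), CDKN2A (2.31-fold) and MKI67 (1.64-fold) were lower, though CDKN2A did not keep its call in every setting chosen beforehand. CDKN1A (log2 0.26, adjusted p = 0.172), CDKN2B (−0.18), IL1A (0.01, but 2.01 with the floor and filter at the 50th percentile) and IGFBP5 (−0.14) did not pass.

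Of 27 SASP genes 19 were higher and 3 (CXCL12, CCL5 and IL15) lower after bleomycin (20 and 3 adjusted over the list alone; adjusted p = 6.9e-15, and adjusted p = 0.0199 with an estimated correlation). Matrix proteases and inhibitors shifted the same way with 14 of 25 higher and 5 lower (14 and 6 adjusted over the list alone; adjusted p = 3.8e-04, and adjusted p = 0.0534 with an estimated correlation). TFPI2 (17.4-fold) and SERPINB7 (4.37-fold) were higher and MMP11, ADAMTS5 (3.36-fold), ADAMTS1, ADAMTS9 and TIMP3 lower. NF-kB regulators were higher as a list (adjusted p = 1.4e-05, and adjusted p = 0.0534 with an estimated correlation), 9 of 19 genes against 1 lower (9 and 1 adjusted over the list alone). IRAK2 (7.87-fold), PTGS2 (6.08-fold), NFKBIZ (3.92-fold) and the feedback inhibitor TNFAIP3 (3.86-fold) were higher and IRF1 lower. Cholesterol synthesis was higher after bleomycin in 14 of 19 genes and lower in none (14 and 1 adjusted over the list alone; adjusted p = 1.1e-11, and adjusted p = 0.0317 with an estimated correlation). FDPS (4.41-fold), EBP (4.07-fold), IDI1 (3.53-fold) and ACAT2 (3.39-fold) led, but IDI1 turned to −0.48 on the log2 scale without probe sets open to shared sequence. Hypoxia and glycolysis genes were higher (adjusted p = 0.00809, and adjusted p = 0.414 with an estimated correlation), 14 of 39 against 4 lower (14 and 6 adjusted over the list alone), among them CA12 (29.2-fold), AK4 (2.49-fold) and ENO2 (1.86-fold), with SLC2A1, MXI1, EGLN1 and BNIP3L lower. The labels give the oxygen level for replicative senescent and young cells and not for bleomycin-treated cells. Leukocyte markers shifted up, with SRGN, PTPRC (2.54-fold) and LCP1 (1.84-fold) higher among 11 and none lower (3 and 0 adjusted over the list alone; adjusted p = 0.00282, and adjusted p = 0.0317 with an estimated correlation). The folds of PTPRC, LCP1 and CA12 depend on the floor, above which these genes lay on 2, 5 and 5 of 6 replicative senescent arrays.

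In mitosis and G2 48 of 58 genes were lower and CKS2 and AURKA higher (2 and 49 adjusted over the list alone; adjusted p = 3.6e-15, and adjusted p = 0.235 with an estimated correlation). The transcription factor FOXM1 (4.33-fold), ASPM (4.31-fold), the kinase CDK1 (4.07-fold) and SPC25 (4.04-fold) were the lowest. ASPM and AURKA did not keep their calls in every setting chosen beforehand. DNA replication and S phase genes shifted down (adjusted p = 0.00756, and adjusted p = 0.540 with an estimated correlation), 17 of 47 with RFC5 alone higher (1 and 18 adjusted over the list alone), among them RFC3 (2.61-fold), TYMS (2.33-fold), MCM7 (2.31-fold) and RRM2 (2.26-fold). RFC5 changed sign with the mean of probe sets. Chromatin proteins reported to change in senescence shifted down (adjusted p = 0.00666, and adjusted p = 0.301 with an estimated correlation), with 11 of 25 lower (1 and 12 adjusted over the list alone), including HMGB2 (3.45-fold) and EZH2 (3.10-fold), and HMGA2 higher (4.40-fold). Of the p53 targets 17 of 33 were lower (2 and 18 adjusted over the list alone; adjusted p = 0.00666, and adjusted p = 0.532 with an estimated correlation), such as TP53INP1 (2.78-fold), SPATA18 (2.76-fold) and ZMAT3 (2.14-fold), and GDF15 (2.78-fold) and TP53I3 higher. Cell cycle inhibitors were lower in 6 of 13 cases and higher in none (0 and 6 adjusted over the list alone; adjusted p = 0.00666, and adjusted p = 0.126 with an estimated correlation), with GAS1 (3.75-fold), the pocket protein RBL1 (2.58-fold) and CDKN1B (2.08-fold) beside CDKN2A. GAS1 and CDKN2A did not keep their calls in every setting chosen beforehand. Fibroblast identity genes were lower, 12 of 22 with PRRX1 alone higher (1 and 13 adjusted over the list alone; adjusted p = 0.00119, and adjusted p = 0.0199 with an estimated correlation). HOXC10 was 2.90-fold, THY1 2.76-fold, DPT 2.76-fold and TWIST1 2.26-fold lower.

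For this comparison 5215 genes passed, 1977 higher and 3238 lower after bleomycin, of which 3170 changed by at least 1.5-fold. With quantile normalization 2649 were higher and 2513 lower, so the excess of lower genes depends on the scaling. The groups did not overlap for 4544 genes (26.3%, where chance gives 0.952% with all arrays as independent samples). Here too the likeness of neighbouring replicative senescent arrays would raise the chance share. With neighbouring arrays averaged 2305 genes passed with the bleomycin arrays as 2 samples. As 1 sample, with no spread of its own, 620 passed (265 higher, 355 lower), all 16 genes with the largest changes among them. Of 79 called genes picked by the naming rule, 36 did not pass there. List members called higher and lower there numbered 14 and 1 for SASP, 7 and 0 for proteases, 7 and 0 for NF-kB regulators, 0 and 2 for p53 targets, 0 and 3 for cell cycle inhibitors, 0 and 4 for mitosis and G2, 0 and 0 for S phase, 1 and 4 for chromatin proteins, 1 and 1 for fibroblast identity, 2 and 0 for leukocyte markers, 10 and 0 for cholesterol synthesis and 1 and 0 for hypoxia. With the replicate number as a block the calls of ADAMTS9 and RFC5 ended. At an intensity floor of 75 the calls of the p53 targets (adjusted p = 0.104), S phase (0.0798) and chromatin lists (0.113) ended, as did that of cell cycle inhibitors there and without probe sets open to shared sequence (0.120). With an estimated correlation 4 of the 12 lists passed (SASP, cholesterol synthesis, fibroblast identity and leukocyte markers). Apart from the estimated correlation, the adjusted p of the 7 lists called at the floor of 75 reached at most 0.0474, for fibroblast identity, and that of leukocyte markers, not tested at that floor, 0.0163. Without bleomycin array 3 the count was 4323. Among genes picked by the naming rule, leaving out 1 array ended the calls of RFC5 (bleomycin array 3, 0.148) and ADAMTS9 (bleomycin array 2, 0.0839).

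Both senescent groups were set against the same young arrays, and 3253 genes changed the same way in both, 1558 up and 1695 down. Genes raised in both included EREG, WFDC21P, MMP3, the histone genes H2BC4 and H1-2, CLCA2, SPP1 and TIGAR, each at least 5.84-fold higher in both comparisons. IL17RD, COL21A1, OLFML1, CHRDL1, POSTN, RNF144A, PTGIS and EGFL6 were at least 12.8-fold lower in both. Another 386 genes went opposite ways. For all 386 the bleomycin and replicative senescent arrays also differed directly. With the same young arrays on both sides, that follows from the opposite calls and adds no support to them. SRGN, IL6, CYP7B1 (6.81-fold up and 4.37-fold down), ASB5, CXCL6, TM4SF1, STC1 and TMEM158 rose after bleomycin and fell in replicative senescence. TMTC1, VIT, COLEC12 (3.04-fold down and 3.12-fold up), PDE8B, SLC38A4, AFF3, ARMC9 and CSRNP3 did the reverse. By list, 23 interferon-stimulated, 20 unfolded protein response, 17 p53 target and 10 histone genes rose in both, and 23 matrix genes fell in both. TMEM158 (adjusted p = 0.0688), SLC38A4 (0.181) and ARMC9 (0.0910) did not pass after bleomycin with neighbouring arrays averaged and the bleomycin arrays as 1 sample. In cholesterol synthesis 6 genes rose after bleomycin and fell in replicative senescence, and 12 mitosis and G2 genes fell after bleomycin and rose in replicative senescence. The mitosis and G2 list itself did not shift for bleomycin against young (camera adjusted p = 0.137, and 0.814 with an estimated correlation). Fewer of its falls there stayed when adjusted over the list alone, so an opposite response of the list is not shown. The genes of these groups were picked by the size of both changes after the values were seen.

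Independent lists of these sizes would share 554 genes up and 539.6 down, and 1114 genes would go opposite ways. The 386 opposite genes were thus fewer than such lists would give. The shared young arrays push both changes the same way, so these products are no exact reference. In 100 simulations of unchanged groups against the young arrays the median count of shared calls was 0 with independent noise (highest 0). It was 8 (highest 26) with noise shared by neighbouring arrays and by all 4 bleomycin arrays. Groups without changes gave few calls that could be shared, at the median 553 for bleomycin and 25 for replicative senescent with shared noise. These counts thus show shared calls from noise alone, and not how many of the real calls would coincide. With the young arrays split 3 and 3, so that each senescent group had separate control arrays, the count over the 20 such assignments was 2251 to 2516 (median 2323.5). Any such split parts neighbouring arrays, so noise shared by neighbours can still link both sets of controls. Across genes, which are not independent replicates, the log2 changes of both comparisons had a correlation of 0.536, against a median of 0.447 (0.425 to 0.483) simulated with independent noise and 0.373 (0.357 to 0.393) with shared noise, and 0.415 to 0.515 with split young arrays. Their covariance was 0.223, against 0.0161 simulated with independent noise and 0.0251 with shared noise. The simulations set both groups against all young arrays, so they are no reference for the values with split young arrays. The simulated correlations come from noise alone, so they do not give the part of 0.536 that the common young arrays made. With neighbouring arrays averaged, 501 genes changed the same way with the bleomycin arrays as 1 sample and 1449 with these arrays as 2 samples.

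**Figure D4:**
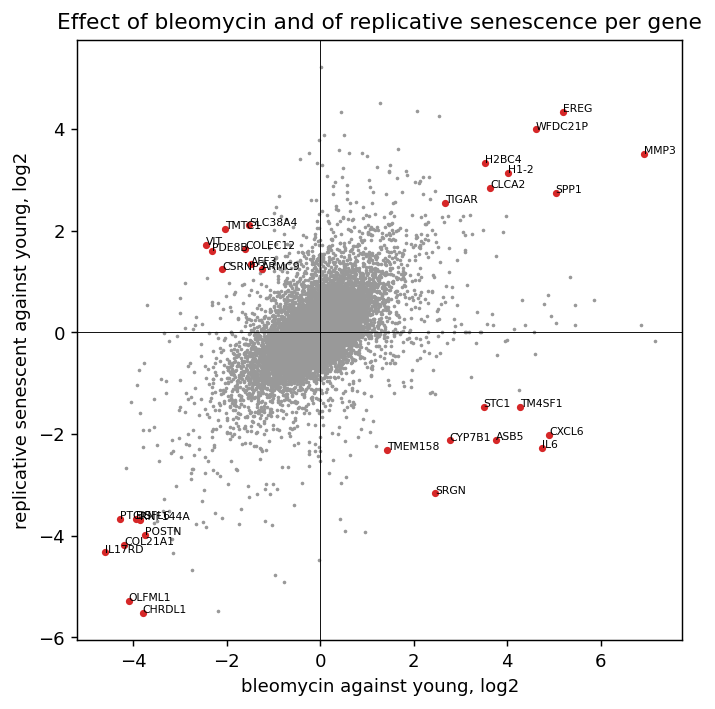
Log2 change of each tested gene in bleomycin against young (horizontal axis) and replicative senescent against young (vertical axis) cells, with the named shared and opposite genes in red. IL6 and CXCL6 lay at 4.75 and 4.90 on the horizontal axis and at −2.27 and −2.02 on the vertical axis.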

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

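The tests of neighbouring arrays as repeats, of rotated residuals, of RNA quality, of same-number batches and of mixed RNA were chosen after the pattern had been seen. Those of scaling, of a shared batch and of other splits were set before their values were computed. Neighbouring arrays of the replicative senescent and young groups were alike. The largest SD between neighbours was 0.914 times the smallest between other arrays in the replicative senescent group and 0.845 times in the young group. These ratios restate the pattern that prompted them, so they do not tell repeats of a culture or RNA from a processing batch. After group and pair position were fitted, neighbours still correlated at −0.162 on average, below the bound of 0 set beforehand for a batch alone but above the −0.5 that array noise by itself would leave. That bound was too high, since a batch alike in both groups leaves only array noise. In a rotation test of the residuals such noise gave −0.666 to −0.297, and the share of rotations that reached the observed value was 0.001, the real one included and the smallest share the test can give. The test assumes noise of equal size on all arrays. A batch acting alike on both groups thus did not account for the likeness alone. Repeats of a culture or RNA, and batches particular to each group, stay open, as does the number of independent samples.

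Mitosis and G2 genes were higher in replicative senescent than in young arrays, both from serum-starved cells, although senescent cells no longer divide. RNA quality did not account for it, since among arrays 1 and 2, with equal ACTB ratios in both groups, the median difference was still 0.94 on the log2 scale. Batches shared by same-numbered arrays did not either, with a lowest median of 0.53 within a pair position (0.94, 1.56 and 0.53 in turn), nor did scaling, with 1.02 under the less favourable of quantile normalization and median centring. The difference between late-passage and young cells that the design names stays open, untested, as a hypothesis found on the same arrays. The young arrays do not stand for cells growing in serum. Whether starvation moved these genes cannot be told, since all groups were starved. With an estimated correlation the list had adjusted p = 0.355, while its call held in the other camera alternatives. The rotation test fry, which tests the list against no change and not against other genes, gave 8.7e-05.

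Replicative senescent array 3 held 16 of the 50 values that stood apart from the rest of their group, among 724 groups of values tested, where chance alone would set about 1 in 20 groups apart. Young RNA mixed into it would lift all young-specific genes by the same share. Over 9 such genes the median share was 0.0492 with an upper quartile 2.39 times the lower, between the bounds set for and against, which leaves mixing open for these genes. The single shares ran from 0.0181 (OLFML1) to 0.205 (FBN2), and the bounds were set after the pattern had been seen. Over 12 cholesterol synthesis genes at least 1.5 times brighter in young arrays than in array 4 the share was 0.452 at the median and 0.311 at the lower quartile, above the highest share of any young-specific gene (0.205), so mixing does not account for those values. Bleomycin RNA was excluded, with a median share of 4.0e-05 over 13 genes, and no biological explanation was tested.

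Cholesterol synthesis separated the senescent groups, with a median log2 difference of 1.17 between bleomycin and replicative senescent arrays (0.34 and −0.72 against young). The 16 values of replicative senescent array 3, all on the log2 scale and with the nearest other array of the group in brackets, were IL17RD 4.94 (3.93), COL21A1 3.99 (3.34), OLFML1 4.29 (3.54), AKR1B10 3.67 (4.52), PTPRC 3.44 (3.37), LAPTM5 5.06 (5.56), CHRDL1 5.24 (3.34), RNF144A 4.15 (3.62), CNTN3 5.25 (3.34), FBN2 8.33 (5.74), EPB41L3 5.81 (3.60), OLFML2A 7.15 (5.77), NDN 5.89 (4.03), THBS1 12.53 (12.73), ACAT2 8.15 (6.98) and the cholesterol list median −0.17 (−0.67). Bleomycin array 1 stood apart for EGFL6 3.81 (3.41), CDKN1C 6.50 (6.25), AURKA 8.35 (8.71), OAS1 7.47 (8.06), PTGS2 11.67 (10.56), CHRDL1 5.02 (5.45), COL14A1 3.88 (3.34), AKR1C2 7.72 (7.39), ABCC3 8.43 (7.97), GAS1 10.10 (9.82), ASPM 6.27 (5.82) and the growth factor list median 0.61 (0.25). Other bleomycin values were MKI67 4.88 (5.41), SHMT2 8.11 (8.19) and CCL5 4.48 (4.84) on array 3, RNF144A 3.67 (3.34), RUNDC3B 4.30 (3.86) and SLC2A1 8.08 (8.26) on array 2, and PHGDH 7.69 (7.87) on array 4. Young arrays gave MKI67 5.33 (5.86), ATF4 11.79 (11.60), FDPS 9.87 (9.69) and ENO2 6.41 (6.95) on array 6, MVK 8.19 (8.03), TNFRSF10C 3.88 (3.50) and the leukocyte list median 0.0327 (0) on array 2, AKR1B10 3.40 (3.35) and CLCA2 3.94 (4.89) on array 4, and INA 3.79 (3.45) on array 3. The remaining replicative senescent values were CDC25B 7.39 (7.55), COL7A1 8.50 (8.25) and AKR1C3 3.49 (3.35) on array 4, PGAM1 11.72 (11.55) on array 5 and TNFAIP3 5.22 (5.66) on array 1. This number of values, 50 of 724, is above the 1 in 20 groups that chance would give, and several lie at or near the floor of 3.34.

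A grouping by chance was tested over 100 splits of the arrays into groups of the same sizes. With arrays counted as independent samples it can be excluded for the gene counts, as only 1 split, the real one, reached the count for bleomycin against young (6486; highest other 4675, with young arrays 1 to 4 set against the rest), for replicative senescent against young (5877; highest other 3058) and for bleomycin against replicative senescent (5215; highest other 853). For the number of lists it cannot, since 5, 8 and 13 of 100 splits reached the real 14, 10 and 12 (highest others 14, 12 and 16). Some splits that did so, such as the one with 16 lists, kept most bleomycin arrays together and held much of the real difference. The list counts thus neither show nor exclude a grouping by chance. All 100 splits treat neighbouring arrays as exchangeable, although in the replicative senescent and young groups they were alike, and the split with 4675 genes keeps neighbours together. Among the 32 splits that part all same-numbered arrays, 1 reached 5877 (highest other 1672). With neighbouring arrays averaged only 10 splits exist, too few for a share under 0.05 (1 of 10, real count 2188, highest other 0).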

How the results depend on the processing

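The alternatives with averaged neighbouring arrays, the random effect, arrays 1 and 2 left out and the floor at 75 were chosen after the data were seen. Counts of changed genes are given in the order bleomycin against young, replicative senescent against young, bleomycin against replicative senescent. They were 6486, 5877 and 5215 in the fit used, and 13279, 11962 and 9661 when every probe set was tested alone. A fold of 1.5 beside the adjusted p left 4149, 3230 and 3170, treat 1464, 1145 and 996, and the rule of the study 1674, 1100 and 1134. With neighbouring arrays averaged they fell to 1077, 2188 and 620 (bleomycin as 1 sample), 3566, 2990 and 2305 (as 2 samples), and with neighbours as a random effect to 3151, 3786 and 1994. Averaging with pair position as a replicate block gave 3700 for replicative senescent against young. Averaging leaves fewer samples, and with bleomycin as 1 sample that group has no spread of its own; how much of the fall came from noise shared by neighbours was not tested. In simulations with such noise, shared also by all 4 bleomycin arrays, and no change, 1003, 160 and 1009.5 genes were called at the median with arrays counted singly. The random effect likewise took the 4 bleomycin arrays as 1 block. Of the called genes picked by rule, 57 of 129, 31 of 120 and 36 of 79 did not pass with averaged neighbours and bleomycin as 1 sample.

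List calls, 14, 10 and 12, came to 2, 0 and 4 with an estimated correlation. The rotation test fry called 20 and 19 lists for replicative senescent against young and for bleomycin against replicative senescent, and the floor at an intensity of 75 left 7 for the latter. Genes changed the same way in both senescent groups numbered 3253, and 6474 over every probe set, 1659 with a fold of 1.5 in both, 501 and 1449 with averaged neighbours (bleomycin as 1 or 2 samples) and 1680 with the random effect. The correlation of both effects, 0.536, moved to 0.566 under the replicate block, 0.471 without arrays 1 and 2, and 0.575 at the floor of 75. With each array left out in turn the counts ranged over 5712 to 6593, 5323 to 5978 and 4323 to 5285 genes, 12 to 16, 10 and 12 lists, 2915 to 3451 genes changed the same way, and correlations of 0.518 to 0.568 (highest without young array 6). No array quality test passed in any of these.

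Bleomycin arrays did not deviate with same-numbered arrays of the other groups (correlations −0.0641 to −0.00250 against young and −0.0813 to 0.0406 against replicative senescent), and 2 of 6 replicative senescent arrays correlated best with the young array of their own number. The replicate block gave 7113 and 5415 genes for the bleomycin comparisons, and the lists of cell cycle inhibitors (adjusted p = 0.111) and leukocyte markers (0.0731) did not pass for bleomycin against young. It changed no list call for replicative senescent against young.

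Some named genes changed sign, and the cause was not tested. Without probe sets open to shared sequence these were, on the log2 scale, MMP11 0.0122, SC5D −0.13, IDI1 −0.72, TKT 0.10 and CALR 0.15 for bleomycin against young, GADD45B −0.13, AKR1C1 0.35 and ABCC3 0.0795 for replicative senescent against young, and IDI1 −0.48 for bleomycin against replicative senescent. IL1A turned to 2.01 (floor and filter at the 50th percentile) and 1.30 (mean of probe sets) for bleomycin against young, and RFC5 to −0.00536 (mean of probe sets) for bleomycin against replicative senescent. The adjusted p-values that follow are the highest over all settings chosen beforehand, including those in which the sign of a gene changed. Of the called genes picked by rule, 24 of 129, 17 of 120 and 9 of 79 kept their sign but not their call in at least 1 setting chosen beforehand, and here too the cause was not tested. With the highest adjusted p over those settings they were CXCL2 0.315, DNM1 0.916, MKI67 0.0602, MMP11 0.972, ADAMTS9 0.0643, MMP16 0.628, MMP2 0.517, TGFB1 0.0625, KITLG 0.701, TGFB3 0.131, DDB2 0.0504, AURKA 0.587, TNC 0.0899, COL7A1 0.282, LOXL3 0.0502, IDI1 0.226, MVK 0.754, PSMB8 0.140, TKT 0.779, SHMT2 0.827, CALR 0.783, RELA 0.0995, IRF1 0.404 and LAPTM5 0.0638 for bleomycin against young, IL1B 0.0588, MMP1 0.0825, ACTA2 0.0918, CDKN1B 0.105, BTG1 0.101, KIF23 0.127, COL10A1 0.985, COL12A1 0.143, FBLN1 0.232, LUM 0.0787, IFI27 0.0849, PSMB9 0.0934, ZNF395 0.853, PFKFB4 0.348, SOD3 0.0630, ABCC3 0.720 and DDR2 0.498 for replicative senescent against young, and CDKN2A 0.486, MMP11 0.916, ADAMTS9 0.0789, GAS1 0.974, RFC5 0.984, ASPM 0.151, AURKA 0.678, EGLN1 0.547 and BNIP3L 0.808 for bleomycin against replicative senescent.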

Other observations

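Lists without a call in any comparison are given with camera adjusted p for bleomycin against young, replicative senescent against young and bleomycin against replicative senescent in turn. They were DNA repair (0.631, 0.473 and 0.177), contractile genes (0.359, 0.758 and 0.333), lysosome (0.297, 0.730 and 0.549), immediate early genes (0.489, 0.608 and 0.234), ribosome genes (0.193, 0.582 and 0.247) and markers of keratinocytes (0.348, 0.730 and 0.470), melanocytes (0.62, 0.998 and 0.458), endothelial cells (0.791, 0.335 and 0.0801) and adipocytes and osteoblasts (0.791, 0.482 and 0.728). In lists called in only some comparisons, the other values were 0.0682 for chromatin proteins and 0.707 for S phase (bleomycin against young), 0.998 for proteases, 0.473 for growth factors, 0.289 for NF-kB regulators, 0.582 for chromatin proteins and 0.389 for leukocyte markers (replicative senescent against young). Without young array 4 the chromatin list passed for bleomycin against young (adjusted p = 0.0429). Hypoxia genes had 0.284 for bleomycin against young. Between bleomycin and replicative senescent arrays, histones (0.198), matrix (0.111), interferon-stimulated (0.861), NRF2 (0.559), unfolded protein response (0.225) and growth factor lists (0.234) did not pass.

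Of the 20 SASP genes raised after bleomycin, 6 also rose and 2 fell in replicative senescence, and SPP1 was among those raised in both. The difference of the SASP list between both senescent groups had adjusted p = 0.0199 with an estimated correlation and passed in the other camera alternatives. It was 8.3e-11 with fry, which tests the list against no change and not against other genes. For SPP1 that difference was 2.29 on the log2 scale.

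Among leukocyte markers SRGN lay at 519 ± 258 in young and 2605 ± 327 in bleomycin arrays (mean ± SD), PTPRC reached 26.5 ± 5.08 in the latter, and 8 of 11 markers did not pass for bleomycin against young. The list value of 0.0497 there ranged up to 0.135 over 17 other alternatives and was 0.162 with an estimated correlation.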
